A study of Mus musculus with 4 samples.

How the data were processed

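The series holds 4 RNA-seq libraries of sorted DP thymocytes, 2 from KO mice and 2 from control mice, grouped by the genotype label of each sample and numbered as in the sample titles. RNA was isolated with a column kit and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.33, aligned with STAR 2.5.2 to mm10 and counted with HTSeq, and edgeR was used by the authors for the comparison. The HTSeq mode, the strand setting and the annotation release are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies may therefore be shared or lost, and such genes are treated as uncertain.

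The deposited values are raw counts per Ensembl gene, 1 file per library plus 1 table of the series, and these hold the same values (0 differing cells over 43430 genes). Gene symbols came from the mm10 annotation for 42462 identifiers and from the authors' table for 46 more. The summary lines of HTSeq that name no gene were left out of library sizes and tests. Reads outside annotated exons, as a share of uniquely aligned reads, came to 17.2% and 18.6% in WT replicates 1 and 2 and to 20.6% and 19.9% in KO replicates 1 and 2, reads of ambiguous assignment to 0.865% to 0.891%, and reads with more than 1 alignment to 24.7%, 23.4%, 23.6% and 23.2% of aligned reads. The authors' deposited comparison gives CPM values per library, which equal the counts scaled by the library total. It also gives log2 fold changes and mean log2 CPM by the authors. Its p-values and adjusted p-values are the authors' own, and the adjustment method is not given in the sources used here. The deposited score of that test is a likelihood ratio statistic, per the file headers. Marks for higher or lower genes in it are the authors', and all marked genes have an adjusted p of at most 0.0092. A filter of at least 1 CPM in at least 2 libraries gives the same 11536 genes as the authors' table.

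Total gene counts were 32846323, 30408863, 34080516 and 31728511 in WT replicates 1 and 2 and KO replicates 1 and 2. Replicates were compared before they were averaged, over 13137 genes with at least 40 counts summed over the 4 libraries. Chi-square per degree of freedom was 9.00 between the WT libraries and 4.82 between the KO libraries, against 5.46 to 12.1 between groups. No libraries held identical values. Pearson correlations of log2 CPM lay between 0.996 and 0.997 across genes, for pairs within and between groups alike.

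The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with filterByExpr (minimum count 10, minimum total 15), TMM factors, robust estimation, group as the only term and Benjamini-Hochberg adjusted p under 0.05. A positive log2 change is higher in KO. Standard errors are the absolute log2 change divided by the square root of the F statistic, and CPM values use TMM-scaled library sizes. On simulated counts for the 13281 tested genes, with 200 genes changed, the test recovered 24 of 50 genes changed 1.25-fold, 35 of 50 changed 1.5-fold, and 48 of 50 each for 2-fold and 4-fold, and 18 of its 173 calls were false. The simulated counts varied more evenly between genes than the real ones (median prior degrees of freedom 52.0 against 6.78), so these figures overstate recovery in the real libraries. In the same simulation camera called a set of genes shifted together and did not call an unchanged set. The simulated genes varied independently of each other. In the real data the estimated correlation within the lists that camera called ran from 0.243 (complex III) to 0.893 (cell cycle). The simulation therefore cannot show how camera with the preset correlation performs on these lists.

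The test, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where said otherwise. The 32 lists were complexes I to IV, ATP synthase, mtDNA-encoded genes, glycolysis, the TCA cycle, pyrimidine synthesis, cholesterol synthesis, DNA methylation enzymes, the integrated stress response, mitochondrial chaperones, antioxidant genes, hypoxia targets, p53 targets, heat shock genes, interferon-stimulated genes, T cell receptor-induced genes, T cell receptor signalling components, NF-kB targets, iNKT selection factors, DP identity, cell cycle, markers of DN thymocytes, mature T cells, NKT effectors, B cells, myeloid, stromal and erythroid cells, and sex-linked genes. The 30 lists with at least 4 tested members were tested with camera (limma 3.58.1; preset correlation 0.01), adjusted over the lists. An estimated correlation and fry were run beside it, and neither called any list. With the estimated correlation the smallest adjusted p was 0.805. With fry the smallest adjusted p was 0.174 (DNA methylation enzymes), and 0.401 in its test for changes in either direction. Named genes were Uqcrfs1, then called genes that passed filters on level, on separation of the groups and on clone names (at most 10 per direction), then up to 4 called members per list or, where none was called, the 2 with the smallest p as values, and Trav11, Traj18 and Cd1d1 as values. Some genes that the rule names are not reported here.

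Shares of 59 Traj genes were computed in 3 blocks with borders at Traj20 and Traj40, with exact Clopper-Pearson 95% intervals and an exact permutation test (scipy 1.17.1, Python 3.11.15). Alternatives covered RLE and upper-quartile factors, no filter on low counts, a CPM filter, DESeq2 1.42.0, edgeR's exact test, limma-voom, the legacy quasi-likelihood fit, removal of mtDNA-encoded genes, the replicate number as a block, leaving out each library, stricter thresholds, and other borders for the Traj blocks. With 1 library left in a group, that library is assumed to vary like the other group. An edgeR likelihood ratio test was added after seeing the data, since the authors' table names that statistic. Tables were handled with pandas 2.3.3 and drawn with matplotlib 3.10.9.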

Results

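RNA was sequenced from CD4+CD8+ double-positive (DP) thymocytes, the stage of T cell development in which the T cell receptor alpha chain is rearranged and invariant natural killer T (iNKT) cells are selected. The cells had been sorted from the thymus of C57BL/6 mice. The 2 knockout (KO) mice carried floxed Uqcrfs1 alleles and a CD4-Cre transgene, which is active from the DP stage. The 2 control mice are labelled wild type (WT) for genotype, while the series description calls them heterozygous littermates, so "WT" is used here only as the name of the group. Each library came from its own mouse. Reads assigned to genes numbered 32846323 and 30408863 in WT replicates 1 and 2, and 34080516 and 31728511 in KO replicates 1 and 2. Xist stood at 2238, 2613, 2554 and 2547 CPM (the count of a gene scaled to a common library total) in that order (log2 change 0.07, SE 0.07, adjusted p = 0.799), and each of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 to 3 counts, so no library differed from the others in sex. The comparison of KO with WT asks what loss of Uqcrfs1 does to the transcriptome of the DP cells from which iNKT cells arise. Whether the controls carried CD4-Cre is not given in the sources used here; if they did not, every difference between KO and WT also includes the transgene.

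Uqcrfs1, which encodes the Rieske iron-sulfur protein of respiratory complex III and is the targeted gene, was lower in both KO libraries than in both WT libraries. It stood at 61.4 and 57.2 CPM in the WT libraries and at 15.6 and 18.6 CPM in the KO libraries. The group means were 59.3 ± 3.0 and 17.1 ± 2.14 CPM (SD, n = 2 per group), a fall of 3.48-fold. On the log2 scale Uqcrfs1 fell by 1.80 with a standard error of 0.09, at an adjusted p of 1.78e-04 in edgeR's quasi-likelihood test. The gene (ENSMUSG00000038462) lies on the minus strand of chromosome 13 from 30540308 to 30545362 in mm10 and has 2 annotated exons, from 30545034 to 30545362 and from 30540308 to 30541341. Counts were deposited per gene, and the floxed exon is not given in the sources used here, so reads from a deleted exon and from retained sequence could not be separated.

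**Figure D1:**
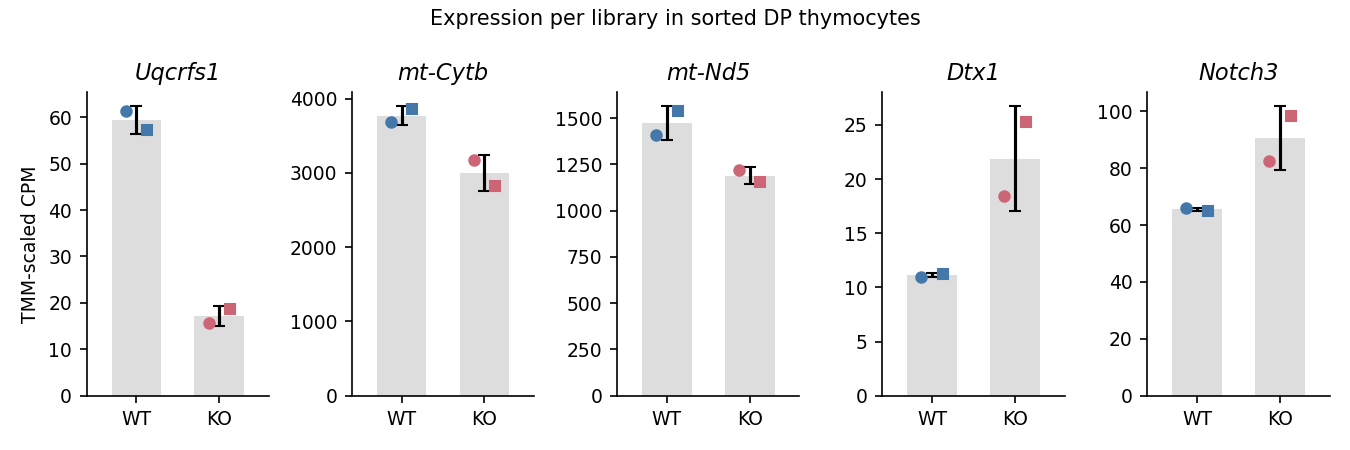
Expression of 5 genes in each library, in CPM after TMM scaling. Grey bars are group means, error bars the SD of 2 libraries, circles replicate 1 and squares replicate 2, with WT in blue and KO in red; Uqcrfs1 stood at 59.3 CPM in WT and 17.1 CPM in KO, while mt-Cytb, mt-Nd5, Dtx1 and Notch3 did not pass the test over all genes.

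Beyond Uqcrfs1, only 2 of the 13281 tested genes passed the threshold in the quasi-likelihood test. Gm47283, annotated on chromosome Y from 90784738 to 90816464 and called Erdr1 in the authors' deposited table, rose from 65.4 ± 7.65 to 119 ± 1.83 CPM (SD, n = 2), a log2 change of 0.86 (SE 0.08, adjusted p = 0.0102). Since each of Ddx3y, Eif2s3y, Kdm5d and Uty had 0 to 3 counts, the reads of Gm47283 are unlikely to come from a Y chromosome. Its locus is therefore uncertain. Gm2420, a transcribed pseudogene on chromosome 5 from 32724352 to 32736194, had 310 counts over the WT libraries and 1 count over the KO libraries. That is a ratio of 323-fold, with an exact binomial interval for counting error of 57.5 to 12779 (adjusted p = 0.0166). Both were named after their values were seen, since the rule for named genes leaves out clone names, and both may share reads with related sequences, so their counts are uncertain. In all, 1 gene rose and 2 fell. At an unadjusted p under 0.05 there were 1116 genes, 584 higher and 532 lower in KO, against 664 expected by chance, and the groups did not overlap for 40.5% of genes, against 33.3% by chance.
The number of called genes depended on the test: DESeq2 called 24 genes and edgeR's exact test 81. It was also higher whichever library was left out, in fits where 1 library of a group is assumed to vary like the other group. Without WT replicate 1 there were 41 calls, without WT replicate 2 there were 365, without KO replicate 1 there were 53, and without KO replicate 2 there were 44.

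Nuclear genes of the respiratory chain were lower in KO as a group, by a small amount. Lower values were seen for 33 of 36 tested complex I genes, 7 of 8 complex II genes, 14 of 15 complex III genes other than Uqcrfs1, 12 of 12 complex IV genes and 14 of 15 ATP synthase genes. The median log2 changes were -0.11, -0.10, -0.10, -0.14 and -0.10 in that order. Uqcrq, a small subunit of complex III, went from 46.4 ± 0.618 to 38.3 ± 0.613 CPM (SD, n = 2), and Ndufa2, an accessory subunit of complex I, from 45.6 ± 2.86 to 36.3 ± 0.09 CPM. These 2 fell when adjusted over the list alone (adjusted p = 0.0222 and 0.0363), and no member of the 5 lists passed over all genes tested. Lyrm7, which assists the insertion of the Rieske protein into complex III, had a log2 change of -0.29 (SE 0.11). Values for the complex II assembly factors Sdhaf1 and Sdhaf4 were -0.37 (SE 0.11) and -0.53 (SE 0.18). The subunits Ndufb9, Cox6b1, Cox6a1, Atp5k and Atp5g2 lay between -0.29 and -0.14.
In camera with a preset correlation between genes, the 5 lists were called lower, with adjusted p values of 2.18e-07, 0.0032, 4.58e-04, 7.41e-05 and 3.82e-04 for complexes I, II, III, IV and ATP synthase. None was called with an estimated correlation (adjusted p = 0.805 for each). Without WT replicate 1 the medians for complexes I, II, III, IV and ATP synthase shrank to -0.04, -0.07, -0.04, -0.05 and -0.04, and only complex I kept its call, at an adjusted p of 0.0220 against 0.168, 0.0534, 0.0902 and 0.187 for the others.

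Transcripts of the mitochondrial genome were lower in KO to a larger extent, with a median log2 change of -0.22 over the 7 genes tested. Values for mt-Cytb, the complex III subunit encoded by mitochondrial DNA, were 3769 ± 124 CPM in WT and 3000 ± 246 CPM in KO (SD, n = 2), a log2 change of -0.33 (SE 0.06). The complex I subunit gene mt-Nd5 stood at 1472 ± 90.9 and 1188 ± 45.9 CPM, a change of -0.31 (SE 0.06). Adjusted over the list alone, 6 genes fell (mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Co1 and mt-Cytb) and 1 rose (mt-Nd6), and 0 passed over all genes tested. mt-Nd6, a complex I subunit gene read from the opposite strand, rose from 11.9 ± 2.59 to 16.6 ± 3.95 CPM in that test (adjusted p = 0.0467), and without a stated strand setting its reads cannot be told from those of its neighbours. The other 6 protein-coding genes of the mitochondrial genome, among them mt-Co2 and mt-Atp6, had 0 counts in every library, so this list covers part of the genome only. The list was called lower by camera (adjusted p = 8.65e-08), and not with an estimated correlation (adjusted p = 0.805).

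Other metabolic and stress gene groups had small median changes. Cholesterol synthesis genes had a median log2 change of -0.066, with 16 of 21 lower, and were called lower by camera (adjusted p = 0.0446), but not with an estimated correlation (adjusted p = 0.805) nor without WT replicate 1 (adjusted p = 0.681), KO replicate 1 (0.0568) or KO replicate 2 (0.0699). Fdft1, the squalene synthase gene, went from 18.0 ± 0.776 to 14.8 ± 0.559 CPM (SD, n = 2), and Mvk, which encodes mevalonate kinase, from 11.1 ± 0.142 to 8.93 ± 0.815 CPM. Glycolysis genes had a median of -0.040 (18 of 20 lower, adjusted p = 0.129), with the glucose transporter gene Slc2a1 at -0.23 (SE 0.11; -0.39 to -0.10 when each library was left out) and Gapdh at -0.12 (SE 0.06; -0.21 to -0.02). The list was called lower without WT replicate 2 (median -0.11, adjusted p = 7.11e-04) and without KO replicate 2 (0.0432), while its median was 0.004 without WT replicate 1. Without WT replicate 2 the TCA cycle and antioxidant lists were also called lower (adjusted p = 0.0172 and 0.00638). Medians were -0.044 for the TCA cycle (adjusted p = 0.308; Suclg1 -0.14, Pdha1 0.08), -0.030 for pyrimidine synthesis (0.316; Uck1 -0.13, Ctps2 -0.07) and 0.040 for DNA methylation enzymes (0.387; Tet3 0.14, Dnmt3b 0.28).
The integrated stress response, which is induced by mitochondrial dysfunction in many cell types, had a median of 0.001 over 25 genes, with 13 higher and 12 lower (adjusted p = 0.885). The median was 0.048 without WT replicate 1 and -0.051 without WT replicate 2. Its members with the smallest p were Cebpg at 0.12 (SE 0.05) and the cystine transporter gene Slc7a11 at -0.24 (SE 0.11; -0.42 to -0.06 when each library was left out). Mitochondrial chaperones had a median of -0.016 (adjusted p = 0.988), with Hspd1 at 0.16 (0.06 to 0.25 over left-out libraries) and Trap1 at -0.07. Antioxidant genes had a median of -0.056 (adjusted p = 0.129), with Gpx4 at -0.15 and Hmox1 at -0.63, and hypoxia targets a median of -0.033 (0.316), with P4ha2 at -0.92 and Ankrd37 at -0.27 (-0.59 to -0.01 over left-out libraries). Heat shock genes had a median of 0.065 (adjusted p = 0.0619). The list was called higher without KO replicate 1 (0.0409), but had a median of -0.006 without KO replicate 2 (adjusted p = 0.773). Hspa8, a constitutive Hsp70 chaperone, rose from 628 ± 12.7 to 742 ± 66.3 CPM when adjusted over the list alone (adjusted p = 0.0341), beside Dnaja1 at 0.12. Hspa8 did not pass over all genes tested (adjusted p = 0.449). For p53 targets the median was 0.017 and the mean -0.025, with camera giving the lower direction (adjusted p = 0.479). Sesn1 fell from 184 ± 12.1 to 156 ± 8.42 CPM over that list alone (adjusted p = 0.0471), but did not pass over all genes tested (adjusted p = 0.443). Bbc3 was at -0.24 (-0.37 to -0.11 over left-out libraries). Over left-out libraries the medians also lay on both sides of 0 for pyrimidine synthesis (-0.075 to 0.020), mitochondrial chaperones (-0.041 to 0.020), hypoxia targets (-0.040 to 0.010) and p53 targets (-0.043 to 0.051). Interferon-stimulated genes had a median of 0.034 (adjusted p = 0.885), with Bst2 at -0.26. Their direction turned with the WT library left out. The list was called lower without WT replicate 1 (median -0.32, adjusted p = 4.11e-05) and higher without WT replicate 2 (median 0.57, adjusted p = 2.05e-05). 

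DP identity genes and factors needed for iNKT selection were not called as groups. The DP identity list had a median log2 change of 0.019 (11 of 15 higher, adjusted p = 0.611), with the co-receptor genes Cd8a at 3199 ± 36.5 and 2978 ± 34.3 CPM and Cd8b1 at 2102 ± 23.5 and 1972 ± 6.20 CPM in WT and KO (SD, n = 2). The iNKT selection list had a median of 0.003, with 7 of 14 genes higher (adjusted p = 0.935). Its median was -0.055 without WT replicate 1 and 0.056 without WT replicate 2. The DP identity median was -0.012 without WT replicate 1. Of the iNKT selection genes Myb, a transcription factor needed for iNKT precursors, stood at 1415 ± 73.1 and 1547 ± 9.95 CPM, and the kinase gene Fyn at 156 ± 2.45 and 169 ± 10.2 CPM. Cd1d1, which encodes the molecule that presents lipid antigen to iNKT cells, stood at 69.2 ± 1.06 and 63.6 ± 8.16 CPM, a log2 change of -0.12 (SE 0.08, adjusted p = 0.696) that ran from -0.26 to 0.00 over left-out libraries.
Genes induced by T cell receptor signalling had a median of -0.038 (adjusted p = 0.233), and were called lower without KO replicate 2 (adjusted p = 0.0456), while their median was 0.012 without KO replicate 1. Among them Id3, an inhibitor of E proteins, fell from 94.1 ± 3.90 to 76.1 ± 7.21 CPM when adjusted over the list alone (adjusted p = 0.0494), but did not pass over all genes tested (adjusted p = 0.417). Egr1 was at -0.13. Medians were -0.018 for components of T cell receptor signalling (adjusted p = 0.325; Cd3g and Cd3d -0.12 and -0.11) and 0.013 for NF-kB targets (0.549; Icam1 0.16, Nfkb1 0.09). Cell cycle genes were lower as a group, at a median of -0.089 with 26 of 28 lower (camera adjusted p = 3.52e-04). This call was lost with an estimated correlation (adjusted p = 0.805), and without WT replicate 1 the list turned to the higher direction, with a median of 0.04 (adjusted p = 0.0902). Tyms, the thymidylate synthase gene, went from 116 ± 10.5 to 98.9 ± 1.90 CPM, and E2f1 from 38.8 ± 3.48 to 34.2 ± 2.53 CPM.

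Genes typical of the preceding CD4-CD8- double-negative (DN) stage were higher in KO. The DN list had a median log2 change of 0.37, with 9 of 10 tested genes higher, and was the only one of the 30 lists tested as sets that camera called higher (adjusted p = 1.67e-06). The call was lost with an estimated correlation (adjusted p = 0.805). Dtx1, a target and regulator of Notch signalling, was at 10.97 and 11.23 CPM in the WT libraries and at 18.4 and 25.3 CPM in KO replicates 1 and 2, a log2 change of 0.98 (SE 0.15). Notch3, a Notch receptor of early thymocytes, was at 65.9 and 65.1 CPM in WT and at 82.5 and 98.4 CPM in KO, a change of 0.47 (SE 0.08). These 2 rose when adjusted over the list alone (adjusted p = 0.00103 and 0.00144) and did not pass over all genes tested (adjusted p = 0.124 and 0.213). Il2ra, which encodes CD25, was at 8.50, 10.5, 12.9 and 26.4 CPM in WT replicates 1 and 2 and KO replicates 1 and 2.

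Of the markers of cells outside the sort gate, summed myeloid markers were high in KO replicate 2 rather than in both KO libraries. They stood at 29.4 and 24.9 CPM in WT and at 24.3 and 61.1 CPM in KO. KO replicate 2 thus stood apart in the same direction as the DN genes. Members under 5 CPM in WT of the B cell, mature T cell and NKT effector lists also had their highest sums there. The full sums of B cell markers (926, 900, 876 and 911 CPM in WT replicates 1 and 2 and KO replicates 1 and 2) and mature T cell markers (1406, 1380, 1321 and 1353) were not highest there. Ighm alone stood at 895, 872, 845 and 876 CPM in that order. Ifngr1 had means of 619 and 562 CPM in WT and KO, and Gimap6 of 443 and 415 CPM. The full sums follow these abundant genes, so they cannot show whether other cells were present. Blnk was higher in both KO libraries, at 1.29 and 1.45 CPM against 0.85 and 0.92 in WT. Lyz2, the lysozyme gene of myeloid cells, was at 0.487, 0.231, 0.499 and 5.36 CPM in WT replicates 1 and 2 and KO replicates 1 and 2. The antigen presentation gene H2-Ab1 had a log2 change of 0.54 (SE 0.31, and -0.02 to 0.94 when each library was left out). The median log2 changes were 0.54 for myeloid markers (10 of 11 higher, adjusted p = 0.240), 0.55 for B cell markers (5 of 6 higher, 0.239; Blnk 0.62), 0.23 for mature T cell markers (11 of 15 higher, 0.308; Ifngr1 -0.14, Gimap6 -0.10) and 0.31 for NKT effector markers (3 of 4 higher, 0.549; Il2rb 0.65, Cxcr6 0.53). For stromal markers the median was -0.17 and the mean 0.12, with the lower direction in camera (adjusted p = 0.549; Col1a1 1.14, Pecam1 -0.09), and 0 of 7 erythroid markers had enough counts for the test. Without KO replicate 1, which leaves KO replicate 2 alone, the mature T cell, myeloid, B cell and NKT effector lists were called higher in KO (adjusted p = 2.89e-11, 2.52e-34, 1.06e-04 and 0.00243). Without KO replicate 2 the mature T cell and myeloid lists were called lower (0.0432 and 0.0141). The myeloid list was also called higher without WT replicate 1 (adjusted p = 0.0409). The NKT effector list turned to the lower direction without KO replicate 2 (median -0.26). The B cell median was 1.27 without KO replicate 1 and 0.18 without KO replicate 2. Over left-out libraries Il2rb ran from -0.66 to 1.33 and Cxcr6 from -0.26 to 1.06.

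**Figure D2:**
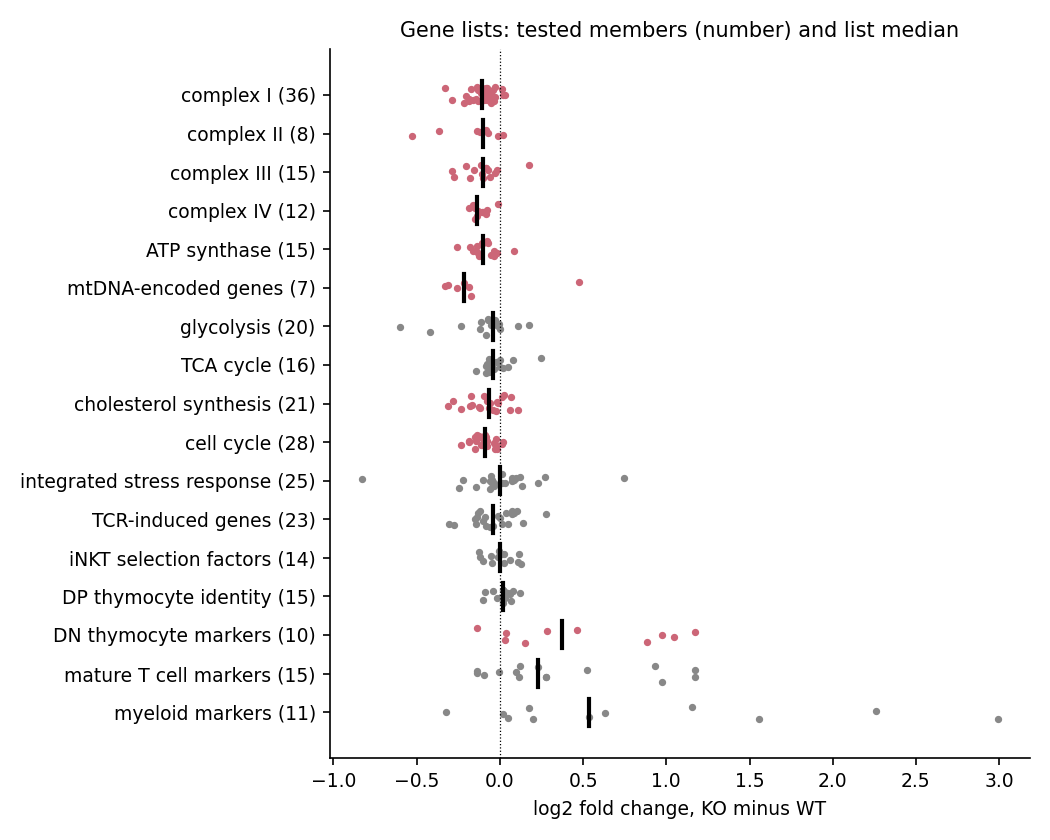
Log2 fold change of KO over WT for the tested members of 17 gene lists, with the number tested in parentheses. Each point is a gene, black bars are list medians and red lists were called by camera with a preset correlation; the medians lie at -0.22 for mtDNA-encoded genes, from -0.14 to -0.10 for the nuclear respiratory lists and at 0.37 for DN thymocyte markers.

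The authors' deposited table, made with edgeR and holding 11536 genes, lists 80 genes at an adjusted p under 0.05, 44 higher and 36 lower in KO. Of these, 76 had an unadjusted p under 0.05 in the quasi-likelihood test, and 12 lie on chromosome 5. Across genes, its log2 fold changes and those computed here had a Pearson correlation of 0.999997 (genes are not independent replicates), so the tables differ in the test rather than in the fold changes. The following genes were chosen after their values were seen. On chromosome 5, Prkag2, which encodes a regulatory subunit of the energy-sensing kinase AMPK, was at 53.6 ± 7.59 CPM in WT and 34.1 ± 0.549 CPM in KO (SD, n = 2), a log2 change of -0.65 (SE 0.09, adjusted p here = 0.115). Galnt11, a glycosyltransferase gene, was at 28.0 ± 5.48 and 15.3 ± 0.623 CPM (-0.88, SE 0.13, adjusted p = 0.124), and Mrpl33, which encodes a protein of the mitochondrial ribosome and overlaps the annotated Babam2, at 71.5 ± 8.42 and 48.6 ± 1.03 CPM (-0.56, SE 0.08, adjusted p = 0.115). Srpk2, a kinase gene for splicing factors, varied widely among controls, at 182 and 279 CPM in WT and 112 and 112 CPM in KO.
The 10 Mb of chromosome 5 from 24100590 to 34100589 held 91 tested genes, 14 of them at an unadjusted p under 0.01, of which 12 were lower and 2 higher in KO. The median over all 91 genes was -0.041.

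**Figure D3:**
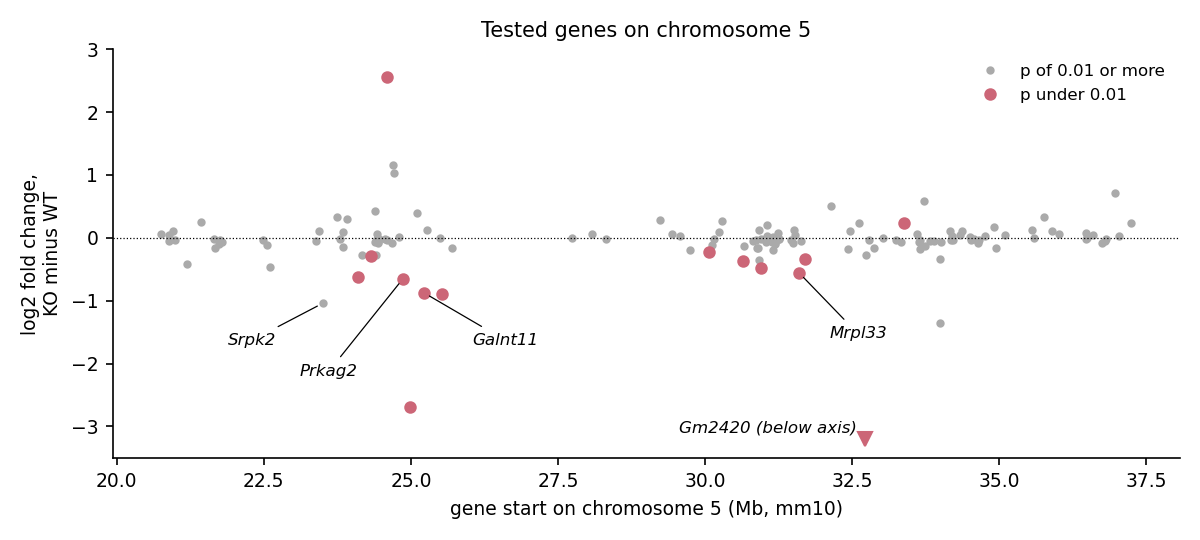
Log2 fold change of KO over WT against gene start for tested genes of chromosome 5 in and around the 10 Mb window from 24100590 to 34100589 (mm10 coordinates in Mb). Each point is a gene, and red points and the red triangle, which stands for Gm2420 below the axis, have an unadjusted p under 0.01; Prkag2, Galnt11 and Mrpl33 lie at -0.65, -0.88 and -0.56, among genes near 0.

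Use of joining segments of the T cell receptor alpha locus was compared because rearrangement proceeds from the 5' to the 3' end of the Jalpha cluster and the invariant receptor joins Trav11 to Traj18. The 3' block (Traj1 to Traj19) held 46.1% of Traj counts in WT replicate 1 (Clopper-Pearson 95% interval 43.2 to 48.9) and 55.2% in WT replicate 2 (52.4 to 57.8). It held 55.2% in KO replicate 1 (52.5 to 57.8) and 57.4% in KO replicate 2 (54.9 to 59.9). The intervals cover counting error only, over 1207, 1338, 1399 and 1516 counts. Group means were 50.6 ± 6.43% and 56.3 ± 1.56% (SD, n = 2), a difference of 5.67 percentage points with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries can give. Without WT replicate 1 the difference was 1.13 points. The 5' block (Traj40 and higher) held 32.3 ± 3.96% in WT and 27.0 ± 0.176% in KO, and the middle block 17.1 ± 2.46% and 16.7 ± 1.38%, with exact permutation p values of 0.333 and 1. Trav11 had 1 count in WT replicate 1 and 0 counts in the other libraries, and Traj18 had 17 and 11 counts in WT and 10 and 21 in KO (log2 change 0.10, SE 0.53, adjusted p = 0.969, and -0.59 to 0.58 over left-out libraries). Too few counts were thus assigned to the invariant segments to compare them. Whether reads of these segments were lost in alignment or counting was not tested.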

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

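Of the tests below, the shuffling of positions on chromosome 5 and the comparison by replicate number were chosen only after the result was seen. The share of uniquely aligned reads that fell outside annotated exons, which enters no test, was 17.9 ± 0.964% in WT and 20.2 ± 0.546% in KO (SD, n = 2), a difference of 2.37 percentage points with both KO libraries above both WT libraries, and drew attention as a signal above the level in the controls. It separates the groups as the median of the mtDNA-encoded transcripts does, and a difference in library makeup or RNA quality was not tested as a cause of the lower mitochondrial or nuclear respiratory transcripts.

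Lower respiratory chain transcripts in KO were weighed against length bias, GC bias and the spread between libraries of a group. Removing the trend on exonic length per gene over other genes moved the median log2 change from -0.105 to -0.078 for the 86 nuclear genes. For the mtDNA-encoded genes it moved from -0.218 to -0.160. The 95% bootstrap intervals of these medians ended at -0.060 and -0.11, and after the trend on GC content at -0.080 and -0.24. The intervals resample the genes of a set, which can vary together, and leave out the spread between libraries. Neither trend removed the shift of the medians, which argues against a bias by GC content as the whole cause in these libraries. The length used was the deposited exonic length per gene, which can exceed the length of a transcript. For Atp5b, annotated from 128083273 to 128090391, it was 7871. The length test therefore cannot decide on a bias by transcript length. For mtDNA-encoded genes the largest difference in median log2 CPM within a group was 0.135 and the smallest between groups 0.206. With 2 libraries per group, this comparison cannot exclude the spread between libraries as the source of the shift. Neither camera with an estimated correlation (adjusted p = 0.805) nor fry (adjusted p = 0.537) called this list. For the nuclear genes the largest difference within a group, 0.113 between the WT libraries, exceeded the smallest between groups, 0.0233, so their shift may come from WT replicate 1, without which 4 of the 5 nuclear lists lost their call (adjusted p = 0.168, 0.0534, 0.0902 and 0.187 for complexes II, III, IV and ATP synthase). A lower level of mtDNA-encoded transcripts after loss of the Rieske protein is a hypothesis that stays open for 6 of the 7 genes measured, since mt-Nd6 was higher. Reads shared with nuclear copies of mitochondrial DNA and a difference in library makeup or RNA quality, which were not tested, stay open beside it. So does the spread between libraries.

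Higher DN thymocyte markers in KO were weighed against a rise of genes of low abundance, DN cells carried through the sort and the spread within groups. The median of the list lay at percentile 100 of 10000 random lists matched on mean expression, whose 95th percentile was 0.11, which argues against a general rise of such genes. Of a second list of 15 DN genes, only 8 were tested. They also had a higher median, 1.26 (95% bootstrap interval 0.40 to 1.57, 7 of 8 higher). Carried-over DN cells, which the gate on CD4 and CD8 should remove, are therefore a candidate explanation. The interval resamples genes and leaves out the spread between libraries. Mycn was lower (-0.24). The tested members include the T cell receptor gamma genes Tcrg-C1, Tcrg-C2 and Tcrg-C4, so the list cannot tell DN thymocytes from gamma-delta T cells. That second list was high mainly in KO replicate 2, with Tcrg-C2 at 1.31, 1.09, 1.44 and 5.80 CPM in WT replicates 1 and 2 and KO replicates 1 and 2, whereas Dtx1 and Notch3 were higher in KO replicate 1 as well. Members of the first list under 5 CPM in WT summed to 4.48, 5.85, 5.31 and 7.88 CPM in the same order. For these, KO replicate 1 lay below WT replicate 2. The largest difference of the first list's median within a group, 0.0880 between the KO libraries, was above the smallest between groups, 0.0722, so the spread between libraries also stays open, as does higher expression of Dtx1 and Notch3 in DP cells themselves, although the Notch targets Nrarp (log2 change -0.14) and Hes1 (1.17, at most 24 counts per library) overlapped between the groups.

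The gathering of genes with p under 0.01 on chromosome 5 was weighed against chance, a segment linked to the targeted allele, and segments that differ between the mice. The densest 10 Mb window held 14 such genes, a number reached in 0.2% of 1000 shuffles of the p-values. The shuffles treat genes as independent, while among the 14 1500035N22Rik lies within Prkag2 and Mrpl33 overlaps Babam2. This share therefore cannot by itself exclude chance placement. Linkage to Uqcrfs1 cannot account for a window on another chromosome. The 10 Mb on either side of Uqcrfs1 held 6 such genes of 90 (exact hypergeometric p = 0.00841). Among them were Hfe and the histone genes Hist1h4i, Hist1h2bc and Hist1h1c, all histone genes lower in KO and lying between 22040636 and 23740367. The hypergeometric test treats genes as independent, which neighbours of 1 family may not be, so its p-value cannot show an excess beyond chance. Whether a flanking segment came with the allele there cannot be told apart from an effect of the deletion. Comparing replicate 2 with replicate 1, which genotype does not set, gave a window of 20 genes on chromosome 4 against at most 12 in 1000 shuffles, so chromosome segments that differ between individual mice may explain the chromosome 5 window as well. WT replicate 1 lay below WT replicate 2, on the side of the KO libraries, for 10 of the 12 lower genes, and no sequence variants were examined here.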

How the results depend on the processing

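The edgeR likelihood ratio test was chosen only after the data were seen, and the other alternatives before. Uqcrfs1 was called lower under its 15 alternatives, with log2 changes of -1.93 to -1.68 when each library was left out. Against 3 called genes (1 higher, 2 lower), there were 191 (114 and 77) with no filter, 24 (12 and 12) with DESeq2, 81 (50 and 31) with edgeR's exact test and 102 (67 and 35) with the likelihood ratio test. There were 4 (2 and 2) with upper-quartile factors or with mtDNA-encoded genes removed, and 3 (1 and 2) with RLE factors, the CPM filter or the legacy fit. In all of these the 3 called genes remained. limma-voom called 2 (1 and 1), without Gm2420, whose log2 change there was -7.44, and stricter thresholds called 1 (0 and 1) at an adjusted p under 0.01 and 2 (0 and 2) with a log2 change of at least 1. Leaving out each library gave 41 to 365 calls (15 to 184 higher, 11 to 181 lower), and the 3 called genes remained each time. The cause was not tested. Of 903 alternative values for 65 named and called genes, 860 kept their call or lack of one, 42 gained a call, 1 lost it and 0 reversed with a call. The 860 include uncalled values of the opposite sign, such as those of Il2rb, Cxcr6 and Traj18 with a library left out.

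With the replicate number as a replicate block there were 27 called genes (18 higher, 9 lower) and 9 called lists, and the call of no list was lost. Deviations from the group means correlated at 0.0912 between libraries of the same number across 13281 genes, and the labels name no litter, batch or day behind a number. Nevertheless 14 genes were called by number, so what libraries of the same number have in common is open.

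Of the gene lists, 9 were called by camera, 9 also with RLE or upper-quartile factors, 12 with no filter, 10 with limma-voom and 8 with mtDNA-encoded genes removed, where that list cannot be tested. With the CPM filter 9 were called, 8 of them shared, since cholesterol synthesis reached 0.0551. Leaving out each library gave 5 (without WT replicate 1, 3 of them shared) to 13. There were 0 with an estimated correlation, at an adjusted p of 0.805 for each of the 9, and 0 with fry, at 0.537 for complexes I, II, III and IV, mtDNA-encoded genes and DN markers, 0.538 for ATP synthase, 0.624 for cholesterol synthesis and 0.786 for cell cycle. Over left-out libraries the adjusted p ran from 4.43e-04 to 0.0534 for complex III, 0.00183 to 0.168 for complex II, 3.72e-09 to 0.0902 for complex IV, 1.58e-07 to 0.187 for ATP synthase and 0.00204 to 0.681 for cholesterol synthesis. It ran from 2.29e-25 to 0.0902 for cell cycle, which turned higher without WT replicate 1. Complex I (1.13e-09 to 0.0220), mtDNA-encoded genes (2.03e-10 to 0.0432) and DN markers (4.40e-17 to 0.00954) kept their call. Lists not called in the full data turned to a call in the lower direction without WT replicate 1 for interferon-stimulated genes (4.11e-05) and without KO replicate 2 for mature T cell markers (0.0432) and myeloid markers (0.0141). Their ranges over left-out libraries, 2.05e-05 to 0.745, 2.89e-11 to 0.929 and 2.52e-34 to 0.397, begin with calls in the higher direction, without WT replicate 2 for the first list and without KO replicate 1 for the others. Among 271 alternative values for the 21 lists not called, 17 gained a call in the same direction, from 10 lists: glycolysis, TCA cycle, antioxidant, heat shock, interferon-stimulated and T cell receptor-induced genes and markers of mature T cells, NKT effectors, B cells and myeloid cells. The cause was not tested.

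The difference in 3' Jalpha share was 4.20 points with 2 blocks split at Traj30, 6.16 without Traj2, and 1.13 (without WT replicate 1) to 10.2 (without WT replicate 2) over left-out libraries. With 1207 to 1516 Traj counts per library, differences of a few points lie within the counting intervals.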

Other observations

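The comparison by replicate number, the grouping by kind of gene and the choice of genes in this part were made only after the data were seen. Libraries numbered 2 differed from libraries numbered 1 at 14 genes in edgeR's quasi-likelihood test with group and number as terms, and 0 of these were among the genes called between the groups. Of the 14, 4 lie on chromosome 4 and 5 on chromosome 14. The chromosome 14 genes include Trav8-2 and Trav16, variable segments of the T cell receptor alpha locus, with 135 and 61 counts in WT replicate 1, 4 and 3 in WT replicate 2, 172 and 93 in KO replicate 1, and 8 and 7 in KO replicate 2. Sall2, a zinc finger transcription factor gene, had 1159, 567, 1184 and 674 counts in the same order, and Ppp1r3e, which encodes a regulatory subunit of protein phosphatase, had 63, 7, 68 and 11. On chromosome 4, Zbtb8a had 146, 12, 192 and 13 counts, Hmgn2, which encodes a nucleosome-binding protein, had 10003, 6334, 9030 and 6367, and Ubxn11 had 1876, 3095, 1830 and 2551. Reads of variable segments can be shared between related segments, so the Trav counts are uncertain.

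Genes annotated as antisense were mostly higher in KO, and the difference from other kinds of gene was not tested. Of 363 tested antisense genes, 227 were higher, the median log2 change was 0.12, and 68 were higher and 9 lower at an unadjusted p under 0.05. For 11345 protein-coding genes the median was -0.003, with 419 higher and 470 lower at that p, and for 282 lincRNA genes 32 were higher and 13 lower. Gm26577, annotated within Myb on the opposite strand, stood at 2.48 ± 0.669 CPM in WT and 8.91 ± 1.59 CPM in KO (SD, n = 2), a log2 change of 1.84 (SE 0.22, adjusted p = 0.0559 in edgeR's quasi-likelihood test). The share of reads outside annotated exons was also higher in both KO libraries (20.6% and 19.9%) than in both WT libraries (17.2% and 18.6%), so the makeup of the libraries differed in the same direction as this group. Without a stated strand setting, reads of these genes cannot be separated from those of their sense partners.

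Several further genes listed in the authors' deposited table had non-overlapping groups here. Tle6, of a family of transcriptional co-repressors, stood at 28.7 ± 2.14 CPM in WT and 18.9 ± 0.0984 CPM in KO (SD, n = 2; log2 change -0.60, SE 0.08, adjusted p = 0.115). Mid1, a ubiquitin ligase gene on chromosome X at the border of the pseudoautosomal region, stood at 9.33 ± 1.46 and 16.5 ± 0.990 CPM (0.82, SE 0.13, adjusted p = 0.138). Gm47283, the called gene that was higher in KO, is annotated in that region on chromosome Y, although Y-linked genes had almost no counts in these libraries. Ptpn14, a tyrosine phosphatase gene, stood at 38.2 ± 8.64 and 56.9 ± 0.609 CPM (0.57, SE 0.14, adjusted p = 0.487). The mitochondrial ribosomal RNA gene mt-Rnr2 had a log2 change of -0.24 (SE 0.05, adjusted p = 0.302), on the same side as most mtDNA-encoded messenger RNAs. The host gene of microRNA 142, Mir142hg, was at 111 and 83.8 CPM (log2 change -0.41, SE 0.05, adjusted p = 0.0661), and the cytokine gene Ltb at 135 and 112 CPM (-0.27, SE 0.06, adjusted p = 0.417).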
